A study of Homo sapiens with 30 samples.

How the data were processed

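Skin rafts are 3-dimensional skin equivalents. Per the labels, dermal fibroblasts from donors with systemic sclerosis (SSc, scleroderma) or from healthy donors were set in a rat tail type I collagen gel, primary human keratinocytes were seeded on top, and the surface was exposed to air so that the epidermal layer stratified. Each raft received nintedanib at 2 uM or vehicle daily and was harvested after 10 days. Poly-A RNA of the whole raft was sequenced on an Illumina platform, so a library holds RNA of both cell types. The 30 libraries form 4 groups: 10 SSc donors and 5 healthy donors, each with 1 vehicle and 1 nintedanib raft. The composition of the vehicle, the source of the keratinocytes and the strandedness of the libraries are not given in the sources used here.

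The deposited table holds 1 column per library and 62714 features in the unit of expected counts, deposited as whole numbers. Per the submitters' processing notes, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 were used with the genome build GRCh38, and RSEM estimates such counts by sharing out reads that map to several genes. The annotation release is not given in the sources used here. Of the features, 62710 were human genes and 4 were reporter or enzyme sequences (cre, egfp, mcherry and tdtomato). A gene symbol was matched to 62639 genes. XIST, related genes and Y-linked genes (527 features) were left out of library sizes and tests, and 62183 genes were used. Coordinates are those of the GENCODE 29 annotation of GRCh38, which was matched to 57762 genes. Because RSEM shares reads between near-identical genes, the values of paralogs such as LGALS7B and GGT1, and of pseudogenes, carry an uncertainty that the tests do not include.

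Library totals ranged from 25.0 to 140 M counts with a median of 44.3 M. The start of the library names in the labels divides the libraries into 3 batches: batch 1 with 4 SSc and 2 healthy donors (25.0 to 43.6 M), batch 2 with 4 SSc and 3 healthy donors (39.2 to 73.4 M), and batch 3 with 2 SSc donors (120 to 140 M). Both rafts of a donor were always in the same batch. The batches were read from these names and are not described in the sources used here. No pair of libraries agreed within sampling noise: over the 2000 most abundant genes, the lowest chi-square per gene of any of the 435 pairs was 74.0.

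Counts were normalized by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr (minimum count 10, minimum total 15), and p-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The nintedanib effects in SSc and in healthy rafts and the difference between them came from 1 fit of all 30 libraries with a term for each donor. SSc was compared with healthy in the 15 vehicle libraries with a term for library batch, and the SSc nintedanib libraries were compared with the healthy vehicle libraries in the same way. Log2 fold changes are given with their standard error (SE), and levels as CPM, the count scaled to the normalized library size (mean ± SD). Tools used in alternatives were limma 3.58.1 and DESeq2 1.42.0.

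The donor term was part of the main design because the labels name the same donor for a vehicle and a nintedanib raft. Deviations from the group means, compared between both libraries of a donor, had a median correlation of 0.498 over the 10 SSc donors, with a lowest value of -0.0926 and 9 of 10 above 0.1. In the 5 healthy donors the correlation was 0.469 to 0.601. The vehicle library correlated best with the nintedanib library of its own donor in 7 of 10 SSc and 5 of 5 healthy donors. Both rafts of a donor shared a batch and batch was not removed, so batch alone can raise these correlations. Without the replicate block, 1101 genes in place of 2314 were called for nintedanib in SSc rafts and 2325 in place of 3928 in healthy rafts.

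The comparisons, their designs, the alternatives, 31 lists of genes for pathways and cell types, and the rule for naming genes were written before the data were examined. The rule took, per comparison, the 10 genes with the largest increase and the 10 with the largest decrease among those called, with a mean log2 CPM of at least 1 and, for the nintedanib effects, the same sign in at least 80% of donors. It passed over pseudogenes and clone names. The rule added the tested receptor targets of nintedanib and up to 4 members of each list with the smallest p. Not every gene that the rule allowed is named. Lists were tested with camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives.

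The balance of cell types was measured per library as the mean log2 CPM (prior count 2) of a fibroblast list of 22 genes minus that of a basal keratinocyte list of 18 genes. This composition score was tested with exact two-sided permutation tests: signs were flipped over donor pairs for the drug, and labels were moved between donors, overall or within batches, for SSc against healthy. The fibroblast list shares 6 genes with the collagen list and 2, PDGFRA and PDGFRB, with the receptor list. A fit with the score as a covariate therefore removes part of any collagen change and of any change of these receptors. The same holds for the basal keratinocyte genes, which are the other part of the score.

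Further alternatives were other size factors, library totals, no filter or a filter at a mean of 1 CPM, DESeq2's Wald test, limma voom, the composition score as a covariate, no replicate block or batch term, single batches and leaving out each donor. An alternative without both healthy donors whose nintedanib library had an outlying mitochondrial share was added after the data were seen. The scripts were tested on simulated counts with 100 genes changed by a log2 of 1 and 99 or 100 by a log2 of 2. For the nintedanib effect in SSc rafts 44% and 89% of them were recovered (21012 genes), in healthy rafts 26% and 62% (20956 genes), and for their difference 12% and 58% (21012 genes). For SSc against healthy vehicle rafts 10% and 63.6% were recovered (19556 genes), and for SSc nintedanib against healthy vehicle 33% and 74.8% (19889 genes). The simulations used the depth and number of donors of this design, with the same mean per gene in all libraries apart from the added changes. They held no differences between donors, batches or cell balance, and genes with low mean counts were not among those changed. These shares therefore need not hold for such genes or beside the shift in cell balance.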

Results

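Gene expression was measured by poly-A RNA sequencing in 30 whole skin rafts, which are cultured skin equivalents with a dermal layer of fibroblasts in collagen gel under a stratified layer of keratinocytes. The fibroblasts came from 10 donors with systemic sclerosis (SSc), a disease with fibrosis of the skin, or from 5 healthy donors. For each donor 1 raft received vehicle and 1 raft received nintedanib at 2 uM for 10 days. Nintedanib is an inhibitor of receptor tyrosine kinases of the PDGF, FGF and VEGF receptor families that is used against lung fibrosis. Library totals were 58.7 ± 37.3 M counts (mean ± SD) in the SSc vehicle group, 59.7 ± 43.6 M in SSc nintedanib, 39.7 ± 9.35 M in healthy vehicle and 42.4 ± 7.54 M in healthy nintedanib. Libraries fell into 3 batches by the start of their names, and batch 3 held 2 SSc donors and no healthy donor.

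The balance of fibroblast and keratinocyte RNA differed between treatments and between donor types. Under nintedanib the mean log2 CPM of the fibroblast list fell by 1.55 in SSc rafts (SD 0.760, n = 10 donors, lower in 10 of 10, exact two-sided sign-flip p = 0.00195). In healthy rafts it was lower by a log2 change of -1.94 (SD 0.558, n = 5, lower in 5 of 5, exact p = 0.0625, the smallest that 5 pairs allow). The basal keratinocyte list, which holds genes of the proliferating layer such as TP63 and KRT15, had a mean change of 1.20 in SSc rafts (SD 1.93, higher in 6 of 10, exact p = 0.0547) and of 2.78 in healthy rafts (SD 0.729, higher in 5 of 5, exact p = 0.0625). The SSc mean was 0.776 without SSc replicate 9 (exact p = 0.109), 1.35 without SSc replicate 1 (exact p = 0.0391), and 1.34 without SSc replicate 2 or 3 (exact p = 0.0469 for each). The composition score, fibroblast minus basal keratinocyte, fell by 2.75 in SSc rafts (SD 2.53, lower in 10 of 10, exact p = 0.00195). Its mean change by batch was -0.986, -3.78 and -4.21 in SSc rafts of batches 1, 2 and 3, and -4.66 and -4.74 in healthy rafts of batches 1 and 2. The change in healthy rafts over all 5 donors was -4.71 (SD 1.01, lower in 5 of 5, exact p = 0.0625). The difference between donor types of 1.96 did not pass an exact permutation test over all donors (p = 0.129). That test did not take batch into account, and no test within batches was run for this difference. The mitochondrial share of counts, tested after the data were seen, rose in SSc rafts from 3.61% ± 0.429 to 4.43% ± 0.863 under nintedanib (SD, n = 10, exact two-sided sign-flip p = 0.00586, higher in 9 of 10), with batch means of the change of 1.33, 0.779 and -0.101. In healthy rafts it was 3.39% ± 0.795 and 4.05% ± 3.10 (exact p = 0.562), with 2 nintedanib libraries at 9.17% and 0.719%. Gene levels are given per whole raft, and each nintedanib effect on genes stands beside these changes.

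**Figure D1:**
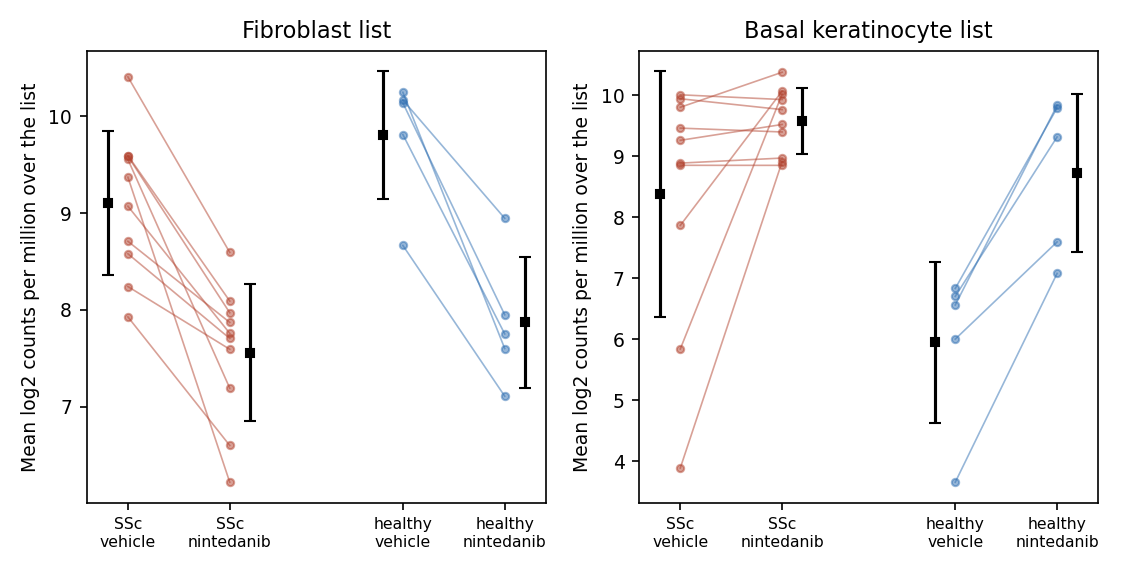
Mean log2 CPM (counts scaled to library size) of the fibroblast list and of the basal keratinocyte list in vehicle and nintedanib rafts, with 1 line per donor, group means as squares and SD as bars. The fibroblast list was lower under nintedanib in 10 of 10 SSc and 5 of 5 healthy donors, and the basal keratinocyte list was higher in 6 of 10 SSc and 5 of 5 healthy donors.

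Among the largest decreases under nintedanib in rafts with SSc fibroblasts were collagen, matrix enzyme and fibroblast activation genes, beside a fall of the fibroblast list as a whole. COL10A1 (ENSG00000123500, GRCh38 chromosome 6, 116118923 to 116158747), a short-chain collagen, fell 27.7-fold, from 23.7 ± 17.9 to 1.10 ± 1.14 CPM (SD, n = 10; log2 fold change -4.79, SE 0.40; edgeR adjusted p = 1.71e-05, Benjamini-Hochberg; lower in 10 of 10 donors). The collagenase gene MMP13 (chromosome 11, 102942995 to 102955734) fell 13.1-fold, from 9.55 ± 14.1 to 0.507 ± 0.338 CPM. ADAM12 (chromosome 10, 126012381 to 126388455), a metalloprotease of activated fibroblasts, fell 7.70-fold (log2 -2.95, SE 0.25), and the fibronectin gene FN1 fell 7.35-fold (log2 -2.88, SE 0.41). Each was lower in 10 of 10 donors.

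Of 28 fibrillar collagen and collagen processing genes, 22 fell and none rose, and 26 fell when adjusted over the list alone. COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632), the main dermal collagen, fell from 3617 ± 3461 to 681 ± 511 CPM (log2 -2.16, SE 0.25, edgeR adjusted p = 0.000148, Benjamini-Hochberg). COL3A1 (chromosome 2, 188974320 to 189012746) fell 4.79-fold (log2 -2.26, SE 0.21) and COL5A1 by a log2 change of -2.05 (SE 0.28). Of 24 matrix metalloproteinases and inhibitors 15 fell (18 adjusted over the list alone), among them MMP14 (log2 -1.70, SE 0.27) and MMP19 (log2 -1.92, SE 0.23). Of 22 TGF-beta response genes 10 fell and 2 rose (13 and 2 adjusted over the list alone), and of 18 myofibroblast contractile genes 10 fell (12 fell and 1 rose adjusted over the list alone). Of 19 genes listed as SSc skin biomarkers 9 fell (12 fell and 1 rose adjusted over the list alone). Of 22 fibroblast genes 17 fell (21 adjusted over the list alone), with a median log2 change of -1.66. Over the 10 SSc donors the mean of the fibroblast list changed by -1.55. The means of the collagen (-1.37), metalloproteinase (-1.39) and TGF-beta response (-0.851) lists did not fall further than that. In the vascular growth factor list 10 of 23 fell (13 adjusted over the list alone). These 7 lists passed camera with the preset and with an estimated correlation (Benjamini-Hochberg adjusted p = 0.00987 to 0.0462). With the composition score as a covariate fewer members fell: 6 collagen, 6 metalloproteinase, 7 TGF-beta response, 3 myofibroblast, 3 SSc biomarker, 7 fibroblast and 1 vascular gene.

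Of the 8 tested receptors that nintedanib inhibits, the transcripts of 5 were called as changed, measured per whole raft. PDGFRA and PDGFRB, the receptors of platelet-derived growth factor, fell 2.89-fold (log2 -1.53, SE 0.28, adjusted p = 0.00284) and 3.22-fold (log2 -1.69, SE 0.28, adjusted p = 0.00152, both edgeR with Benjamini-Hochberg), each in 10 of 10 donors. FGFR1 fell (log2 -1.44, SE 0.28), as did the VEGF receptor FLT1 (log2 -1.82, SE 0.43), while FGFR4 rose (log2 1.96, SE 0.48) at a level of 2.13 ± 1.13 CPM. The changes of PDGFRA, PDGFRB and FGFR1 lay near the mean change of the fibroblast list (-1.55), which includes PDGFRA and PDGFRB. FGFR2 (log2 0.84), FGFR3 (1.66) and KDR (0.74) did not pass the test. Of the 8 receptors tested, 3 rose and 4 fell when adjusted over the list alone, and the list had no common direction in camera (adjusted p = 0.134). With the composition score as a covariate edgeR called 0 of the 8, with a log2 change of -0.55 for FGFR1, -2.03 for FLT1 and 1.26 for FGFR4.

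Among genes that rose were NPNT (chromosome 4, 105894775 to 106004027), a basement membrane ligand of integrins, 12.7-fold (log2 3.67, SE 0.52; 1.22 ± 1.61 to 15.7 ± 21.3 CPM), SCN4B, a sodium channel subunit (log2 3.31, SE 0.61), and RYR1, a calcium release channel (log2 3.29, SE 0.49), each higher in 10 of 10 donors. In the cholesterol synthesis list 9 of 22 genes rose, such as MVK (log2 0.74, SE 0.16), and 19 rose and 1 fell when adjusted over the list alone. Camera called that list (adjusted p = 1.48e-08), but not with an estimated correlation (adjusted p = 0.182 with an estimated correlation). In the inflammatory list 13 of 28 genes fell and 2 rose (17 and 4 adjusted over the list alone, adjusted p = 0.168 with an estimated correlation). CXCL5, a neutrophil chemokine, fell (log2 -2.68, SE 0.29), as did the cytokine gene IL11 (log2 -2.56, SE 0.35). Of 24 ERK and growth factor feedback genes 6 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 0.386 with an estimated correlation), among them ETV1 (log2 -1.52, SE 0.28) and SPRY1 (log2 -1.19, SE 0.24), whose transcripts follow ERK signalling. With the composition score as a covariate edgeR called 0 cholesterol genes and 0 ERK feedback genes, and 2 inflammatory genes fell.

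Few single genes of the keratinocyte lists were called in SSc rafts, while camera with the preset correlation called the basal (adjusted p = 3.76e-05), suprabasal (0.000347), cornified (0.0453) and wound (0.0329) lists as higher, after Benjamini-Hochberg adjustment. Per donor the mean of the basal list was higher in 6 of 10. That of the suprabasal list was higher in 5 of 10 (mean change 1.31, exact two-sided sign-flip p = 0.203; 0.762 without SSc replicate 5 and 0.855 without SSc replicate 9), and that of the cornified list in 3 of 10 (0.762, exact p = 0.418). In the basal list 3 of 18 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.386 with an estimated correlation). BCAM, a laminin receptor, rose (log2 2.62, SE 0.46), and COL7A1, the anchoring fibril collagen, fell (log2 -1.16, SE 0.22, lower in 10 of 10). Of 18 suprabasal genes 1 rose, and 0 were called when adjusted over the list alone (adjusted p = 0.4925 with an estimated correlation). Of 27 cornified envelope genes and of 18 wound and stress genes edgeR called 0, over all genes and adjusted over the list alone, with 1 in each list at an unadjusted p under 0.05 and 1 called by each of DESeq2 and limma voom. Their adjusted p was 0.717 and 0.694 with an estimated correlation. With the composition score as a covariate 7 basal, 12 suprabasal, 10 cornified and 13 wound genes were called lower and 0 higher by edgeR. The basal genes are part of the score, and nintedanib itself lowered its fibroblast part (mean log2 change -1.55). The covariate alone can therefore turn keratinocyte genes lower, so these calls do not show a decrease in keratinocytes.

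In total edgeR called 2314 of 21386 genes (978 up, 1336 down), of which 1263 changed at least 2-fold. Scaling by library totals in place of TMM gave a median log2 change of 0.112 (-0.00406 with TMM) and called 1592 up and 964 down, and no called gene changed its sign. With the composition score as a covariate 549 genes were called, 174 of them among the 2314, and 59 of the 2314 changed sign. COL10A1 (log2 -4.00), ADAM12 (-2.42), COL1A1 (-2.07), COL3A1 (-1.76) and MMP13 (-2.79) were among those still called, and PDGFRA (log2 -0.78, adjusted p = 0.197, edgeR with Benjamini-Hochberg) and PDGFRB (-0.92, adjusted p = 0.121) were not. Both receptors are members of the fibroblast list in the score, so this fit cannot show whether the cell balance accounts for their decrease. Within batches 1 and 2, 225 and 330 genes were called, and in batch 3, with 2 donors, edgeR called 0 (1674 at an unadjusted p under 0.05; other tools were not run there). Without SSc replicate 6 the count was 1393 and without SSc replicate 9 it was 1495.

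**Figure D2:**
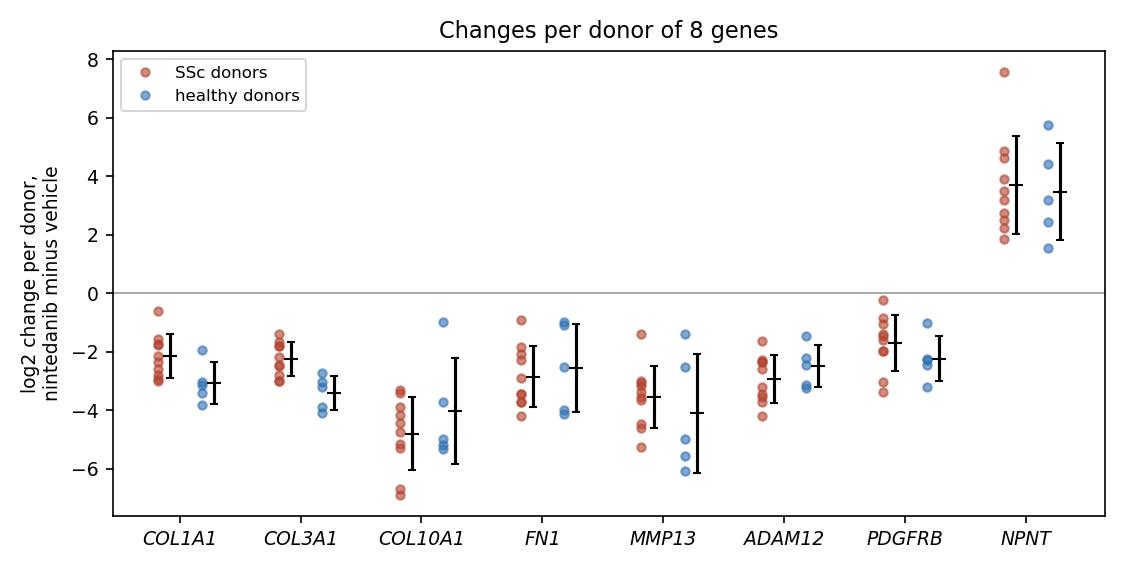
Log2 change in CPM, nintedanib minus vehicle, of 8 genes, with 1 point per donor and the mean ± SD per donor type. COL1A1, COL3A1, COL10A1, FN1, MMP13, ADAM12 and PDGFRB lie below 0 in 10 of 10 SSc and 5 of 5 healthy donors, and NPNT lies above 0 in all of them.

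In rafts with healthy fibroblasts many collagen genes were lower and many keratinocyte genes higher under nintedanib, measured per whole raft. Camera with an estimated correlation called 0 of 31 lists there. COL3A1 fell 10.6-fold, from 5424 ± 3291 to 527 ± 327 CPM (SD, n = 5; log2 -3.40, SE 0.30; edgeR adjusted p = 4.06e-05, Benjamini-Hochberg; lower in 5 of 5 donors). COL1A1 fell 8.48-fold (log2 -3.08, SE 0.36), COL10A1 26.4-fold (log2 -4.72, SE 0.62) and MMP13 19.0-fold (log2 -4.25, SE 0.71). VCAM1, a leukocyte adhesion molecule, fell 17.8-fold (log2 -4.16, SE 0.72). TP63 (chromosome 3, 189631416 to 189897279), the master regulator of basal keratinocytes, rose 10.3-fold, from 10.9 ± 7.75 to 110 ± 96.1 CPM (log2 3.36, SE 0.65), in 5 of 5 donors.

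Of the 18 basal keratinocyte genes 17 rose and 1, COL7A1 (log2 -1.60, SE 0.31), fell, with the same counts when adjusted over the list alone. The list had a median log2 change of 3.13, but camera did not call it with an estimated correlation (adjusted p = 0.239 with an estimated correlation). Of 18 wound and stress keratinocyte genes 11 rose (16 adjusted over the list alone), such as KRT6A, a keratin of wounded epidermis (log2 3.18, SE 0.89), and AREG, a ligand of the EGF receptor (log2 3.02, SE 0.58). Of 18 suprabasal genes 8 rose (10 adjusted over the list alone) and of 27 cornified envelope genes 7 rose (10 adjusted over the list alone), among them SPRR1B (log2 3.73, SE 0.91). The adjusted p with an estimated correlation was 0.272, 0.411 and 0.444 for these 3 lists. GCNT2, a glycosyltransferase, had among the largest increases (log2 4.83, SE 0.86).

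Of the 28 collagen genes 25 fell (27 adjusted over the list alone), with a median log2 change of -1.91, and the adjusted p was 0.0952 with an estimated correlation. Of the 22 fibroblast genes 17 fell (21 fell and 1 rose adjusted over the list alone), and of 28 matricellular genes 16 fell and 1 rose (18 and 1 adjusted over the list alone), with an adjusted p of 0.122 with an estimated correlation for each. POSTN, a matrix protein of remodelling skin, fell from 1396 to 224 CPM (log2 -2.95, SE 0.57). Of the 8 receptors, PDGFRA (log2 -2.23, SE 0.39), PDGFRB (log2 -2.25, SE 0.39) and FGFR1 (log2 -1.60, SE 0.39) fell and FGFR3 (log2 2.65, SE 0.85) rose (2 rose and 4 fell adjusted over the list alone). Of 28 interferon response genes 8 fell, over all genes as over the list alone, among them XAF1 (log2 -2.29, SE 0.35) and MX2 (log2 -2.16, SE 0.44), while the adjusted p was 0.510 with an estimated correlation. Of the 24 ERK and growth factor feedback genes 6 rose and 3 fell, over all genes as over the list alone, with a median of 0.22, and camera did not call the list (adjusted p = 0.149). In the inflammatory list 8 rose and 3 fell (8 and 5 adjusted over the list alone). Its median (-0.22) and its mean (0.40) differed in sign, and camera did not call it (adjusted p = 0.869).

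In total edgeR called 3928 of 21386 genes (2265 up, 1663 down), of which 2694 changed at least 2-fold. Camera called 15 of 31 lists with the preset correlation and 0 with an estimated one, and fry called 15. With the composition score as a covariate 128 genes were called, 50 of them among the 3928, and 1091 of the 3928 changed sign. COL1A1 (log2 -2.93), COL3A1 (-2.55), COL7A1 (-2.64) and XAF1 (-3.52) were still called, while KRT6A had a log2 change of -1.05. TP63, a member of the basal list in the score, had a log2 change of 0.23 (edgeR adjusted p = 0.862, Benjamini-Hochberg). Of the 28 collagen genes 2 then fell, and of the 18 suprabasal genes 5. In the basal, suprabasal, cornified and wound lists 0 genes rose in that fit, with medians of -0.65, -1.985, -2.26 and -1.64. The basal genes are part of the score, which limits what these values show. Without Healthy replicate 5, 6 or 1 the counts were 1321, 1541 and 1685, and within batches 1 and 2 they were 1936 and 253.

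**Figure D3:**
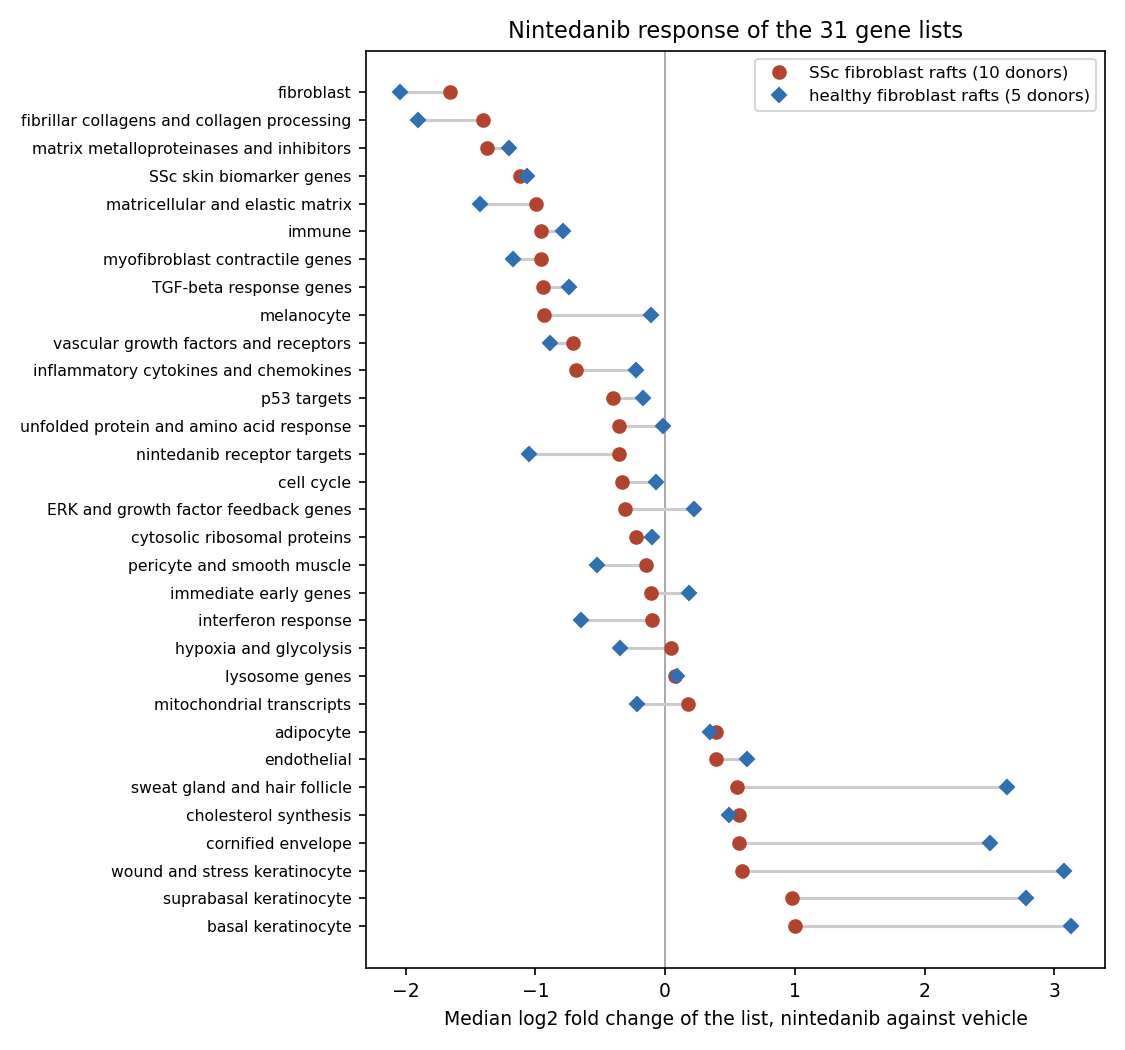
Median log2 fold change (horizontal axis) of each of the 31 gene lists for nintedanib against vehicle in SSc and in healthy fibroblast rafts, with 1 pair of points per list. The collagen list lies at -1.40 in SSc and -1.91 in healthy rafts, and the basal keratinocyte list at 1.00 and 3.13.

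The nintedanib effects in SSc and healthy rafts were compared over genes and by a test of their difference. Of the genes called in both, 586 rose in both (103.6 expected from the 2 counts) and 823 fell in both (103.9 expected), and 4 went opposite ways. Across genes the log2 changes had a Pearson correlation of 0.680 and a Spearman correlation of 0.668, and genes are not independent replicates. The composition score fell in both donor types (-2.75 in SSc and -4.71 in healthy rafts), and a shared shift in cell balance alone favours such agreement. With the score as a covariate 174 of the 2314 SSc calls and 50 of the 3928 healthy calls remained. The difference itself was called by edgeR for 1 gene, ARHGEF34P (chromosome 7, 144272445 to 144286966; log2 -2.07, SE 0.25, adjusted p = 0.00555, Benjamini-Hochberg), an unprocessed pseudogene named here after its value was seen. Its level was 28.2 in vehicle and 36.4 in nintedanib SSc rafts and 5.92 and 30.2 CPM in healthy rafts, and reads shared with related genes limit these values. DESeq2 called 165 genes and limma voom 1, and 1961 had an unadjusted p under 0.05 in edgeR. PDGFRA differed by a log2 of 0.70 (SE 0.46, adjusted p = 0.651) and PDGFRB by 0.56 (SE 0.47, adjusted p = 0.729), which did not pass edgeR's test with Benjamini-Hochberg adjustment. Camera called 15 of 31 lists for the difference with the preset correlation, but 0 with an estimated correlation and 0 by fry. The call of ARHGEF34P was lost with no replicate block (1822 genes at an unadjusted p under 0.05) and without both healthy donors with an outlying mitochondrial share (2657), and the count was 8, 4 and 2 without SSc replicates 9, 6 and 5. Within batch 1 alone 996 genes were called, and in batch 2 edgeR called 0 (725 at an unadjusted p under 0.05; other tools were not run there).

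Before drug, single genes of hypoxia and collagen processing had lower levels, and some epidermal genes higher levels, in SSc than in healthy rafts. Camera with an estimated correlation called 0 of 31 lists in this comparison. P4HA1, a collagen prolyl hydroxylase, was lower by a log2 change of -1.41 (SE 0.19, edgeR adjusted p = 0.0158, Benjamini-Hochberg; 131 ± 60.2 in 10 SSc and 309 ± 75.2 CPM in 5 healthy rafts). LOX, which crosslinks collagen, was lower by -1.54 (SE 0.25), the mitophagy receptor BNIP3 by -1.44 (SE 0.25) and PDK1, an inhibitor of pyruvate oxidation, by -1.66 (SE 0.31). EYA1, a developmental transcription cofactor, was 15.1-fold lower (log2 -3.92, SE 0.74), and APLN, a peptide hormone induced by low oxygen, was 10.3-fold lower (log2 -3.36, SE 0.64). CD9, a tetraspanin of epithelial cells, was 5.73-fold higher (251 ± 165 against 44.0 ± 26.9 CPM; log2 2.52, SE 0.41), and LGALS7B, a galectin of stratified epithelia whose reads are shared with its paralog LGALS7, was 27.2-fold higher (log2 4.76, SE 0.96). MYC, a growth regulator, was higher (log2 1.17, SE 0.25).

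In the hypoxia and glycolysis list 2 of 20 genes were lower over all genes and 7 when adjusted over the list alone. The median log2 difference was -0.74, and 19 of 20 genes were lower (camera adjusted p = 1.42e-06, adjusted p = 0.390 with an estimated correlation, fry adjusted p = 0.0469). The mean level of this list was lower in SSc rafts by -0.770 pooled (exact permutation p = 0.00333), by -0.812 within batches (exact p = 0.00571), by -0.365 in batch 1 (exact p = 0.4) and by -1.16 in batch 2 (exact p = 0.0286). In the collagen list 2 of 28 were lower over all genes and 9 when adjusted over the list alone (median -0.93, adjusted p = 0.390 with an estimated correlation).

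The keratinocyte lists had higher levels in SSc rafts without a call over all genes. In the basal, suprabasal, cornified and wound lists edgeR called 0 genes over all genes, while 16 of 18, 17 of 18, 24 of 27 and 16 of 18 were higher when adjusted over the list alone and also at an unadjusted p under 0.05. DESeq2 called 16, 17, 23 and 15 of them and limma voom called 0. The list medians were 2.91, 3.59, 4.45 and 3.39, and the adjusted p was 0.390 with an estimated correlation for each. TP63 had a log2 difference of 3.17 (SE 0.95, edgeR adjusted p = 0.0730, Benjamini-Hochberg) and KRT1 of 5.82 (SE 1.61, adjusted p = 0.0666). The mean of the basal list was higher in SSc rafts by 2.43 pooled (exact permutation p = 0.0320), 2.81 within batches (exact p = 0.00762), 4.63 in batch 1 (exact p = 0.0667, the smallest possible) and 1.40 in batch 2 (exact p = 0.2). In the fibroblast list edgeR called 0 of 22 genes over all genes (1 higher and 9 lower at an unadjusted p under 0.05, 8 called by DESeq2 and 1 by limma voom). Of these genes 6 were lower when adjusted over the list alone, and the median was -0.90 (adjusted p = 0.479 with an estimated correlation). In the receptor list edgeR called 0 of 8 over all genes (2 higher and 3 lower adjusted over the list alone and at an unadjusted p under 0.05, 5 called by DESeq2 and 0 by limma voom).

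**Figure D4:**
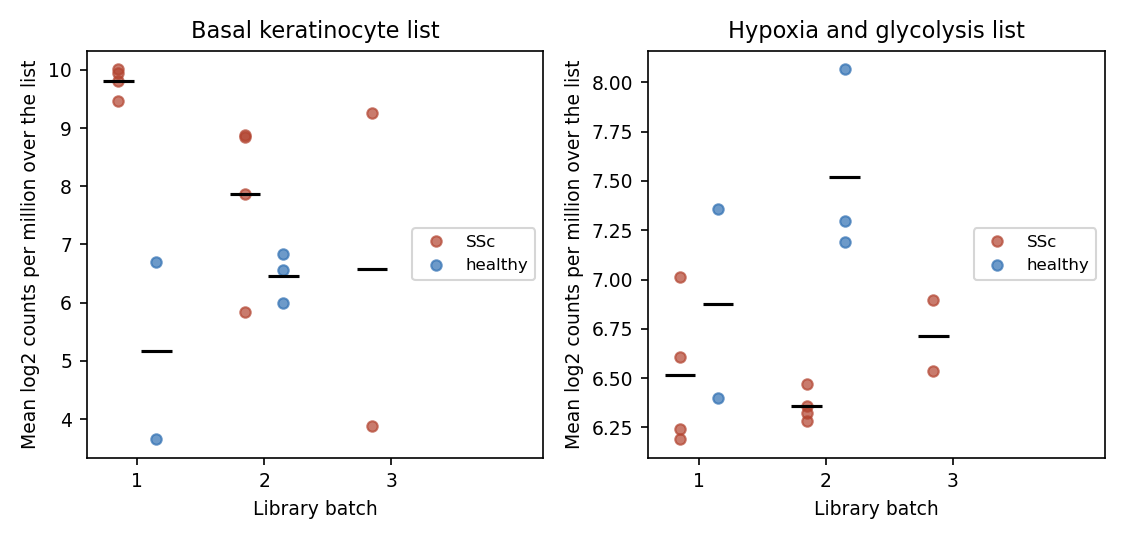
Mean log2 CPM of the basal keratinocyte list and of the hypoxia and glycolysis list in the 15 vehicle libraries by library batch, with 1 point per library and black bars for the means. The SSc minus healthy difference of the basal list was 4.63 in batch 1 and 1.40 in batch 2, and that of the hypoxia list was -0.365 and -1.16.

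Of 19492 genes, edgeR called 139 (45 higher, 94 lower in SSc). The balance of directions depended on the setting. The share of calls that were higher in SSc was 32.4% here and 35.85% with limma voom. It was 59.46% with DESeq2, 52.69% in batch 1 alone and 68.26% without SSc replicate 9. Leaving out any of the 15 donors moved the count by more than 1.5 times, from 0 without SSc replicate 7 (4699 at an unadjusted p under 0.05) to 2098 without SSc replicate 9. The count was 0 with the composition score as a covariate (2879 at an unadjusted p under 0.05), 10 without the batch term, 159 with limma voom and 3843 with DESeq2. In batch 1 alone 2995 genes were called, and in batch 2 edgeR called 0 (2149 at an unadjusted p under 0.05). With the score in the model P4HA1 differed by a log2 of -1.25, LOX by -1.09, BNIP3 by -1.53 and PDK1 by -2.11, with edgeR adjusted p of 0.216 to 0.285 (Benjamini-Hochberg).

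SSc rafts under nintedanib were compared with healthy vehicle rafts, and the nintedanib effect was set against the SSc difference. Keratinocyte genes were higher and matrix genes lower in treated SSc rafts than in healthy vehicle rafts. Of 18 suprabasal genes 18 were higher, of 18 basal genes 17 were higher and 1 lower, with the same counts when adjusted over the list alone, and of 27 cornified genes 24 were higher (25 adjusted over the list alone). Of 28 collagen genes 23 were lower (26 adjusted over the list alone) and of 22 fibroblast genes 20 were lower (21 lower and 1 higher adjusted over the list alone). The adjusted p with an estimated correlation was 0.0881 for the suprabasal list and 0.116 for the basal, cornified, collagen and fibroblast lists. Of the 8 receptors 3 were higher and 5 lower, over all genes as over the list alone. In total edgeR called 7930 of 19914 genes (4189 higher, 3741 lower), and 51 with the composition score as a covariate, where 1747 of the 7930 changed sign. Batch and donor type cannot be separated for the 2 SSc donors of batch 3, and within batch 1 alone 2196 genes were called.

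Of the 139 genes that differed between SSc and healthy vehicle rafts, 15 (10.8%) had a nintedanib effect in SSc rafts of the opposite sign. Of the 33 called in both comparisons, 32 went the same way and 1 the opposite way. These counts share the SSc vehicle libraries and have no value for no effect beside them. To avoid shared vehicle libraries, the SSc difference from some donors was compared with the nintedanib effect in others, and across genes the Pearson correlations were 0.372 and 0.549 (Spearman 0.437 and 0.433). The composition score was lower in both comparisons (-3.13 for SSc minus healthy vehicle, pooled, and -2.75 for nintedanib in SSc rafts). A shared shift in cell balance alone favours a positive correlation, and no value with the score in the model was computed. With all donors in both the Pearson correlation was 0.461. Log2 levels simulated with no effect gave a mean of -0.908. In that simulation the differences between donor types were removed from the donor means, so the shared vehicle libraries alone force a strongly negative value. It is therefore not the value that these data would give without an effect, and no conclusion is drawn from it. In treated SSc rafts against healthy vehicle rafts 45 of the 45 higher genes were called higher and 90 of the 94 lower genes lower, over 19139 genes tested in both. Both of these comparisons used the same healthy vehicle libraries, which alone favours shared calls, and no value for no shared difference was computed.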

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

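The tests of library batch for the collagen decrease and for the keratinocyte RNA were chosen after the results were seen, as were the slopes of the tracking genes and the splits within batches, and list medians and counts with the composition covariate had been seen before any prediction was written.

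Within groups, 14 of 218 sets of 5 or 10 values had a highest or lowest value far from the others by Dixon's ratio. Chance gives such a gap in about 1 in 20 groups, or 10.9 of them. In the SSc vehicle group 1 library had 4.95% of its counts in ribosomal protein genes, and the next had 3.04%. In the healthy vehicle group the lowest fibroblast mean was 8.67 on the log2 scale (next 9.81). Another library of that group had the lowest basal keratinocyte mean (3.65, next 6.00), the lowest suprabasal mean (1.81, next 4.00) and the highest composition score (6.51, next 3.69). Levels in the healthy vehicle group stood apart for TP63 (-0.69), ITGA6 (2.09) and ARHGEF28 (2.00), and in the SSc vehicle group for ARHGEF28 (1.90). Among log2 changes under nintedanib in SSc donors the value farthest from the rest was 7.57 for NPNT, 5.33 for CDKL2, -0.43 for TMC4, 7.03 for KRT15 and -5.25 for CTHRC1.

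The nintedanib effect differed between SSc and healthy rafts for the pseudogene ARHGEF34P, with a log2 difference of -2.07 by edgeR's test of the difference. Camera with the preset correlation called 15 lists for the difference, and their median log2 differences were -2.23 for basal keratinocyte, -2.46 for wound and stress keratinocyte, -2.07 for cornified envelope, -1.63 for suprabasal keratinocyte and -0.71 for sweat gland and hair follicle genes. The others were -0.84 for inflammatory genes, -0.59 for ERK and growth factor feedback genes, -0.37 for unfolded protein response genes, -0.28 for immediate early genes, 0.57 for collagens, 0.56 for interferon response genes, 0.52 for fibroblast genes, 0.42 for matricellular genes, 0.39 for mitochondrial transcripts and 0.18 for hypoxia genes. With an estimated correlation camera called 0 of these lists, as did fry. Outside the human genes, egfp had 83 counts in 5 libraries, of which 72 were in 1 library (0.00027% of its counts), while cre, mcherry and tdtomato had 0 counts in all 30 libraries.

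Collagen genes fell under nintedanib in SSc rafts, and a lower share of fibroblast RNA was tested as an explanation. The mean of the collagen list changed by -1.37 (SD 0.516, 10 of 10 donors lower), while 55 genes outside the lists that track the composition score in vehicle rafts changed by -0.506 (SD 0.643), a difference of -0.865 (SD 0.525, exact two-sided sign-flip p = 0.00391, 9 of 10 donors), although the tracking genes had a steeper slope on the score in vehicle rafts (0.218 against 0.162). An offset between library batches leaves no change within donors, since both rafts of a donor shared a batch. The design therefore argues against it. The change within donors was below 0 (exact two-sided sign-flip p = 0.00195, batch means -0.905, -1.75 and -1.55), but this p restates the decrease and is no separate test of batch. The collagen list thus fell further than the tracking genes, but not further than the fibroblast list, with which it shares 6 genes. That list changed by -1.55, with batch means of -0.923, -2.16 and -1.56. The tracking genes were chosen by a score that also holds keratinocyte genes, so they may understate a loss of fibroblast RNA. A lower share of fibroblast RNA may therefore account for part or all of the decrease, and this test cannot decide. Lower collagen transcription per fibroblast, or a change in the kind of fibroblast, stays open as a hypothesis, since the pattern was found and tested on the same data.

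The share of keratinocyte RNA was larger in SSc than in healthy vehicle rafts. The fibroblast list was lower by -0.799 within batches (exact two-sided p = 0.0495 with labels permuted within batches). CPM are shares, so these values cannot tell more keratinocyte RNA from less fibroblast RNA. Batch as the whole cause is argued against by the difference within batches of 2.81 log2 units in the basal list (exact two-sided p = 0.00762 with labels permuted within batches), although batch 2 alone gave 1.40 (exact p = 0.2). The labels give the same numbers of fibroblasts and keratinocytes seeded for all 30 rafts. An effect of the donor type on the epidermis and the amount of each layer taken at harvest could each account for it and were not tested.

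Hypoxia and glycolysis genes were lower in SSc than in healthy vehicle rafts. With the composition score in the model the SSc coefficient was -1.23 (within-batch permutation p = 0.00190), farther from 0 than without the score. Moved labels do not keep the link between the score and donor type, so this p may be too small. In the gene tests with the score edgeR called 0 of 20 genes of the list (median log2 -0.94). The coefficient did not shrink with the score, but composition as a source is not excluded. With labels permuted within batches the difference was -0.812 (exact two-sided p = 0.00571), which argues against batch, although batch 1 alone gave -0.365 (exact p = 0.4). Donor type, raft thickness and oxygen supply may each be sources and were not tested.

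Other divisions of the libraries were drawn to ask whether chance alone gives as many called genes. For nintedanib in SSc rafts 1 of 50 splits, the real one, called as many as 2314 genes, and the highest other count was 1, which argues against chance. For healthy rafts the 16 possible splits are too few for a share under 0.05, with 3928 genes in the real split (1 of 16) and 188 in the highest other. For the difference between donor types 3 of 50 splits called at least 1 gene, and the highest other count was 2458, so chance cannot be excluded. Which donors that split relabelled was not examined. For SSc against healthy vehicle rafts 2 of 100 splits over all libraries called at least 139 genes, and the highest other count was 1644. How many healthy donors that split kept was not examined. With labels moved within batches, a test chosen after the results were seen, 100 of 525 possible splits were drawn. Of these 1, the real one, called as many, and the highest other count was 3. This argues against chance within batches, but the count still ranged from 0 to 2098 when each donor was left out. For SSc nintedanib against healthy vehicle rafts 1 of 100 splits called as many as 7930 genes, and the highest other count was 2826. Within batches it was also 1 of 100, with 1129 as the highest other count, which argues against chance alone.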

How the results depend on the processing

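The tests without both healthy donors with an outlying mitochondrial share and the agreement of both nintedanib effects with the composition covariate were chosen after the data were seen, and the other alternatives were planned.

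For nintedanib in SSc rafts (2314 genes) the count was 1263 at 2-fold or more, 4251 with DESeq2's Wald test, 3679 with limma voom, 549 with the composition covariate, 1101 with no replicate block, 225, 330 and 0 within batches 1, 2 and 3, and 1393 (without SSc replicate 6) to 2580 when each donor was left out, with 1495 without SSc replicate 9. For healthy rafts (3928) it was 5953 with DESeq2, 128 with the covariate, 2325 with no replicate block, 1936 and 253 within batches 1 and 2, and 1321 (without Healthy replicate 5) to 4970 when each donor was left out, with 1541 and 1685 without Healthy replicates 6 and 1. For their difference (1) it was 3 with no filter, 165 with DESeq2, 5 with the covariate, 996 within batch 1, and by edgeR 0 with no replicate block (1822 at an unadjusted p under 0.05), 0 within batch 2 (725) and 0 without both healthy donors with an outlying mitochondrial share (2657). It was 1 to 8 when each donor was left out: 8 without SSc replicate 9, 4 without SSc replicate 6 and 2 without SSc replicate 5.

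For SSc against healthy vehicle rafts (139) it was 254 with library totals, 70 with no filter, 449 with a mean of at least 1 CPM, 3843 with DESeq2, 10 with no batch term, 2995 within batch 1, and by edgeR 0 with the covariate (2879 at an unadjusted p under 0.05), 0 within batch 2 (2149) and 0 without both healthy donors with an outlying mitochondrial share (3894). Leaving out each donor gave 0 to 2098: without SSc replicates 1 to 10 in turn 5, 42, 5, 1, 1679, 1343, 0, 10, 2098 and 2033, and without Healthy replicates 1, 2, 3, 5 and 6 it gave 1, 7, 71, 36 and 46. For SSc nintedanib against healthy vehicle rafts (7930) it was 5256 at 2-fold or more, 51 with the covariate, 2196 within batch 1 and 6827 to 8699 when each donor was left out. A 2-fold limit removes genes by construction, and for the rest the cause was not tested.

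Lists called by camera numbered 22, 15, 15, 11 and 17 of 31 in the 5 comparisons as reported, and 7, 0, 0, 0 and 0 with an estimated correlation. Fry called 0 for the difference and 2 for SSc against healthy vehicle rafts. The change and the SSc minus healthy difference of the composition score kept their sign with the suprabasal list and when each donor was left out (SSc change -2.97 to -2.24), as did the correlations between effects in their alternatives. With the suprabasal list the exact p was 0.00781 for the SSc change, 0.0625 for the healthy change and 0.0114 for the vehicle difference within batches. The exact p of the score with a donor left out is not given here. Within single batches the exact p of the vehicle difference was 0.0667 in batch 1, the smallest possible there, and 0.143 in batch 2.

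Of the values of single named genes under alternatives, 3449 were the same, 686 weaker, 33 stronger and 20 reversed. With the composition covariate the log2 change in SSc rafts was -0.28 for FGFR2 and -0.46 for FGFR3, and in healthy rafts it was -1.81 for KLK9, -1.08 for FGFR2, -1.51 for FGFR3, 0.70 for KDR, -1.05 for KRT6A, -0.21 for KRT17, -0.92 for KLK5, -0.82 for SPRR1B, -0.79 for PERP, -1.37 for OVOL1 and -0.72 for IL36G. In SSc rafts KDR was -0.26 with no replicate block and -0.22 within batch 2, and FGFR2 was -0.0634 within batch 1. In healthy rafts FGFR2 was -0.80 within batch 1, and KDR ranged from -0.999 (without Healthy replicate 2) to 0.10 (without Healthy replicate 1). With the covariate PDGFRB was -0.012 for the difference, and ITGA6 was -0.061 for SSc against healthy vehicle rafts. The cause was not tested. What limits the number of calls (depth, donors, composition or batch) was not compared.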

Other observations

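The tests of the suprabasal and cornified lists by batch were chosen after the results were seen, as was the choice of genes in this part, while the edgeR tests and the lists were planned.

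COL7A1, the collagen of anchoring fibrils below the basal layer, moved against the other basal keratinocyte genes. It fell in healthy rafts (log2 -1.60, SE 0.31) while 17 of 18 genes of its list rose, and it fell in SSc rafts (log2 -1.16, SE 0.22), in 10 of 10 and 5 of 5 donors. It stayed called by edgeR with the composition score in the model, at a log2 of -1.77 in SSc rafts (adjusted p = 0.00224, Benjamini-Hochberg) and -2.64 in healthy rafts (adjusted p = 0.00838). In that fit its list moved the same way: 7 of 18 basal genes fell and 0 rose in SSc rafts (median -0.96), and 2 fell and 0 rose in healthy rafts (median -0.65). COL7A1 and the other basal genes are part of the score, so this fit cannot separate their change from that of the cell balance. In the 4 SSc donors of batch 1, where the basal list changed by 0.063 on average, the suprabasal list changed by -0.572 and the cornified envelope list by -0.757, each lower in 4 of 4 donors. In batches 2 and 3 the cornified list changed by 1.5 and 2.32 on average, and over all 10 SSc donors by 0.762 (exact two-sided sign-flip p = 0.418, higher in 3 of 10), or by 0.233 without SSc replicate 5 and 0.227 without SSc replicate 9.

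KRT8, a keratin of simple epithelia, rose under nintedanib in SSc (log2 2.60, SE 0.37) and healthy rafts (log2 3.31, SE 0.53), in 10 of 10 and 5 of 5 donors. With the composition score as a covariate KRT8 was still called by edgeR in SSc rafts (log2 1.82, adjusted p = 0.0419, Benjamini-Hochberg) but not in healthy rafts (log2 1.97, adjusted p = 0.248). The annotated region of KRT8 on chromosome 12 (52897187 to 52949954) adjoins KRT18, which limits the separation of their reads. CD163, a scavenger receptor of macrophages, fell in SSc rafts from 23.7 ± 25.1 to 2.79 ± 3.58 CPM (log2 -3.63, SE 0.59). With the composition score as a covariate it was not called by edgeR (log2 -2.06, adjusted p = 0.111, Benjamini-Hochberg). Of 32 cytosolic ribosomal protein genes 32 were higher in SSc than in healthy vehicle rafts (median log2 0.53), and edgeR, DESeq2 and limma voom called 0 of them (4 at an unadjusted p under 0.05 in edgeR), with an adjusted p of 0.734 with an estimated correlation for the list.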
